A study of Mus musculus with 3 samples.

How the data were processed

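Gene expression was measured on Affymetrix arrays in leukaemic cells from 3 mice, 1 array per mouse. Total RNA was extracted with the Qiagen RNeasy Micro kit and labelled with biotin using the Affymetrix 3' IVT Express kit, per the labels' protocols. The deposited values were log2 signals per probe set, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of each probe set. The RMA version and the set of arrays that was normalized together were not given in the sources used here. If arrays outside these 3 were normalized with them, each value depends in part on those arrays. The deposited values carried no detection call. The values of the 3 arrays stood in 2 deposited tables, whose largest difference was 0. A further 3 columns of per-sample values belonged to samples outside the series and were not used here.

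Each array held 45101 probe sets, of which 64 were control probe sets. In the platform annotation used here, 34958 probe sets named 1 gene, 932 named several genes and 9211 were unnamed. Gene symbols were updated through the gene identifier in a reference gene table (assembly GRCm38.p6, used for names only), in which 34754 of the 34958 probe sets had a match and 204 kept the older symbol. Probe sets that named several genes were left out of all gene values, with the exception of 4 adult globin probe sets described among the closing observations. A gene's level was that of the probe set with the highest mean over the arrays, which gave 18194 genes, 9012 of them with 2 or more probe sets. Probes differ in affinity, so the levels of different genes were not set against each other.

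A gene counted as detected in an array when its log2 signal was above the 95th percentile of that array's signals for 113 genes of families that leukaemic T cells should not express (olfactory, vomeronasal, trace amine and taste receptors and keratin-associated proteins). A separate list of genes typical of other tissues served as a check of this threshold. The members of 36 gene lists (32 by gene name and 4 by name pattern, including the receptor families that set the background) were fixed before the data were examined. The named lists held 549 measured genes. A further 57 names had no probe set naming that gene alone in the annotation and were not analysed here.

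The design has 1 group, so no test between groups was run and no p-value is given. Levels are means ± SD over the mice, n = 3. The number of arrays limits the precision. The range of a gene is its highest minus its lowest mouse on the log2 scale, and genes with a range over 1 (over 2-fold) were counted among those detected in all 3 arrays. The shift of a list in a mouse is the median, over its members detected in all 3 arrays, of that mouse's signal minus the mean of the other mice. It was set beside the central 95% (2.5th to 97.5th percentile) of 10000 random lists of the same size, matched on mean signal in 20 bins. Lists with fewer than 3 detected members had no shift. The second-brightest detected probe set of a gene with a range over 1 was checked for the same highest and lowest mouse. That share was set beside 1000 draws of randomly paired probe sets of similar mean signal and range. Signals near the 3' and the 5' end of control transcripts were compared within each array.

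Genes named in the report follow a rule fixed before the data were examined. It takes the first 6 measured members of each described list, members on the unlikely side of detection where these are 8 or fewer, the 25 detected genes with the largest range, and up to 4 members with the largest deviation for a list outside the central 95%. Genes outside this rule are said to have been chosen after their values were seen.

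The steps were tested on simulated data with the typical spread between these arrays (SD 0.14). For the count of genes with a range over 1, run on 9854 simulated genes, 0 of 50 genes changed by 0.5 in 1 mouse were called, as were 29 of 50 changed by 1, 50 of 50 changed by 1.5 and 50 of 50 changed by 2.5. None of the 9853 genes of a second set without any change was called (0 genes). With 1 spread of 0.14 for every gene, a range over 1 was hardly possible there. For the list shifts, a list of 25 genes shifted by 0.3 was recovered at 0.29, and 4 of 96 unshifted list values lay outside the central 95%. The simulated noise was independent between genes. Real genes differ in spread and members of a list vary together, so these rates of false calls need not hold for the real data. Second probe sets of genes changed in 1 mouse gave the same highest and lowest mouse in 29 of 60 cases, since the order of the other mice was left to chance.

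Alternatives covered the choice of probe set, probe sets prone to cross-hybridisation, the scaling between arrays, a repeated quantile normalization, the other deposited table, other detection thresholds and filters, a larger range, the summary of a list, and leaving out each mouse in turn. A pair of further alternatives was added after the data had been seen. All steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.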

Results

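The transcriptome of a mouse T-cell acute lymphoblastic leukaemia (T-ALL) clone, #483, was measured after growth in recipient mice. Recipients were 3 C57BL6/J mice given a sublethal dose of 7.5 Gy, and leukaemic cells were recovered by their green fluorescent protein (EGFP) 20 days after transfer. The labels describe every mouse as a biological replicate, so the data form 1 group of 3 samples, called mouse 1, mouse 2 and mouse 3 here. Bone marrow and spleen are both named as sources for the series as a whole, and the labels do not say which organ each array came from. The design addresses what the clone expressed in its hosts and how far independent recipients differed. The arrays had median log2 signals of 5.62, 5.63 and 5.61, and their background thresholds lay at 5.86, 5.92 and 5.79.

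Of 18194 genes, 9510 (52.3%) were above background in all 3 arrays, 1177 in some and 7507 in none. All 20 measured widely expressed genes were detected, among them Actb at 13.96 ± 0.05, Gapdh at 13.47 ± 0.02 and Hprt at 11.64 ± 0.13 (log2 signal, mean ± SD, n = 3, as for all levels below). Cytosolic ribosomal protein genes were detected in 45 of 49 cases, with a median range between mice of 0.08. Among 26 genes typical of liver, heart, brain, skin and other distant tissues, 5 (19.2%) also passed the threshold. These were Apoa1 (6.14 ± 0.07), Ttr (6.18 ± 0.05), Ins2 (6.33 ± 0.07), Prm1 (6.97 ± 0.14) and Mbp, a myelin gene that lymphoid cells also transcribe (10.70 ± 0.17). Detection close to the threshold therefore carries little weight for a single gene.

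The T cell programme was present in every recipient. All 21 measured T cell identity genes were detected, including the CD3 chains of the T cell receptor complex, Cd3e (10.47 ± 0.18), Cd3d (12.73 ± 0.10), Cd3g (11.96 ± 0.11) and Cd247 (10.66 ± 0.53). The proximal signalling kinase Zap70 was at 10.55 ± 0.14 and the adaptor Lat at 12.42 ± 0.12. Of 17 measured genes of the CD4 CD8 double-positive thymocyte stage, 15 were detected in all arrays. The coreceptor genes Cd4 (8.20 ± 0.39), Cd8a (11.88 ± 0.27) and Cd8b1 (11.42 ± 0.51) were among them, as were the recombinase genes Rag1 (12.98 ± 0.18) and Rag2 (9.62 ± 0.52) and the terminal transferase gene Dntt (10.77 ± 0.71). The exceptions were Cd69, a marker of activation and positive selection, which was below background in all arrays (4.35 ± 0.33), and Id3, an inhibitor of E proteins, which was above it in some.

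Genes of the earliest thymic progenitors were less uniformly detected, with 8 of 19 above background in all arrays, 5 in some and 6 in none. Il2ra, the CD25 gene of the double-negative stages, was at 9.26 ± 0.19, Lyl1 at 8.35 ± 0.48 and Lmo2 at 6.34 ± 0.07. Kit, the stem cell factor receptor, reached 6.99 in mouse 3 and lay below background in mouse 1 (4.31) and mouse 2 (4.70). Il7r, the interleukin-7 receptor chain, was at 9.75 in mouse 3 and below background in mouse 1 (4.57) and mouse 2 (5.84). Cd44 was likewise above background in only some arrays. Of 22 genes of mature and peripheral T cells, 5 were detected in all arrays. The egress and lymph node homing genes S1pr1 (5.02 ± 0.08) and Ccr7 (4.84 ± 0.28) were below background, whereas Gzma, a granule protease of cytotoxic lymphocytes, was at 11.87 ± 0.30.

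Among genes implicated in T-ALL, 29 of 42 were detected in all arrays, 2 in some and 11 in none. Notch1, the receptor most often activated in this leukaemia, was at 12.27 ± 0.17, and Myc at 11.31 ± 0.08. Tal1 (4.65 ± 0.33) and Lmo1 (4.91 ± 0.07), oncogenes that define particular T-ALL subtypes, were below background. Transcriptional targets of Notch were detected in 16 of 21 cases. The ubiquitin ligase gene Dtx1 was at 12.48 ± 0.22, the repressor gene Hes1 at 8.95 ± 0.69, the feedback regulator gene Nrarp at 9.22 ± 0.24, Notch3 at 10.81 ± 0.12 and Ptcra, the pre-T cell receptor alpha chain, at 12.19 ± 0.25. These are levels within 1 clone, and no normal T cells or other leukaemias were compared with them. Array signals report RNA and do not show whether the Notch receptors were active.

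**Figure D1:**
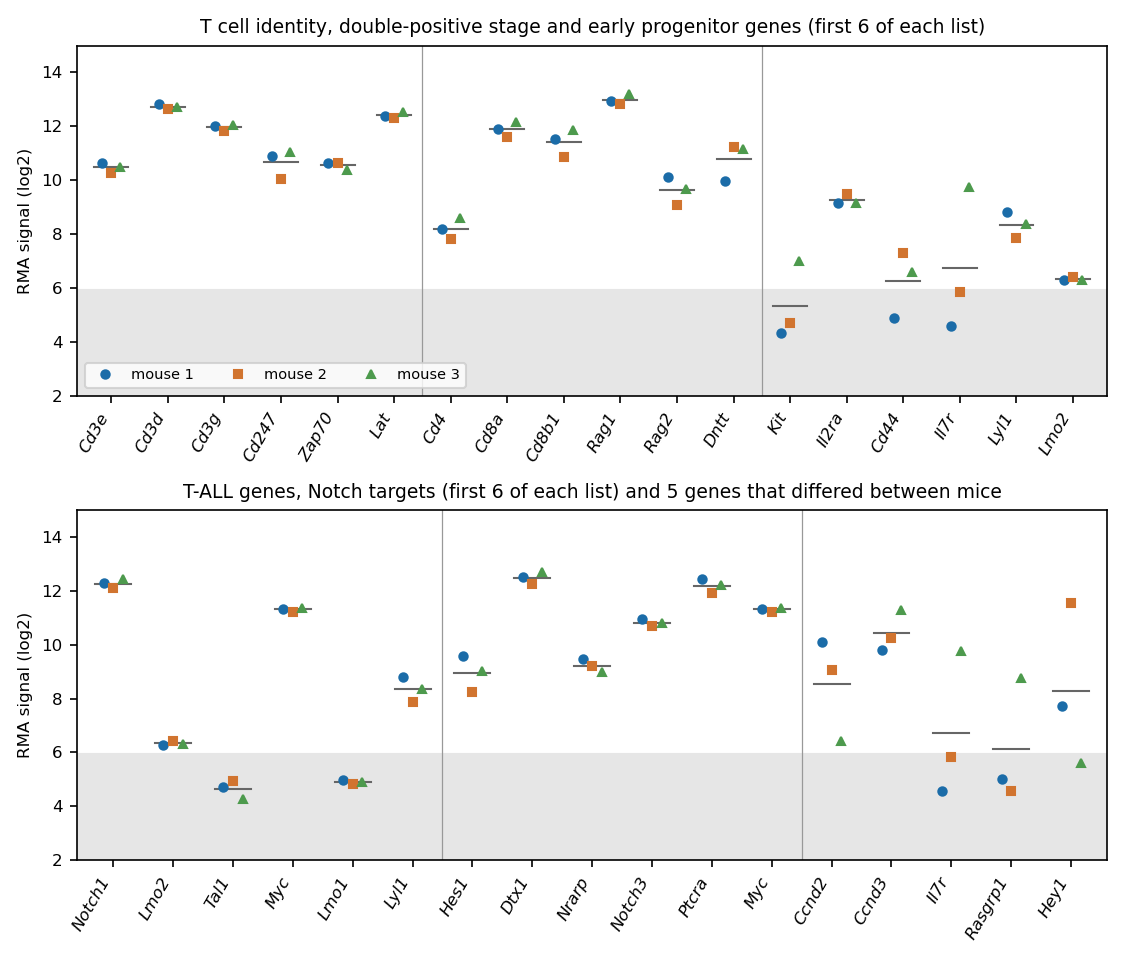
RMA signal (log2) of each mouse for genes of T cell identity, of the double-positive and early progenitor stages, of T-ALL and of the Notch pathway, with the mean of 3 mice as a line and grey shading up to the highest background threshold of the arrays. Notch1 sits at 12.27 on average and Tal1 in the shaded zone. The rightmost 5 genes were chosen after their values were seen. Of these, Ccnd2, Il7r, Rasgrp1 and Hey1 are spread over several log2 units and Ccnd3 over 1.48. For Ccnd3, only 1 of 3 detected probe sets gave the order shown.

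Genes of proliferation and growth were detected throughout. All 25 measured genes of G1 and S phase and all 25 of G2 and M phase were above background in every array, including the proliferation marker Mki67 (12.56 ± 0.17), the replication clamp Pcna (13.51 ± 0.22), the replicative helicase subunit Mcm2 (11.52 ± 0.23), the mitotic kinases Cdk1 (11.29 ± 0.19) and Aurka (10.36 ± 0.21) and topoisomerase Top2a (12.39 ± 0.29). The same held for 24 of 24 Myc target and ribosome biogenesis genes, such as nucleolin (Ncl, 13.39 ± 0.03) and fibrillarin (Fbl, 12.58 ± 0.10), and for 23 of 23 genes of the PI3K and mTOR pathway, such as Mtor (9.26 ± 0.16) and Rptor (8.98 ± 0.17). Among regulators of apoptosis, 11 of 15 BCL2 family genes were detected. The antiapoptotic genes Mcl1 (11.60 ± 0.02), Bcl2l1 (9.27 ± 0.33) and Bcl2 (6.99 ± 0.68) were among these, together with the proapoptotic Bcl2l11 (9.96 ± 0.39).

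Metabolic and stress genes were present to different extents, where 52.3% of all genes passed in every array. Glycolysis genes were detected in 14 of 15 cases, with Hk2 at 8.16 ± 0.32, Pfkl at 7.88 ± 0.42 and Aldoa at 11.74 ± 0.41, and genes of the hypoxia response in 12 of 16, without Vegfa (4.93 ± 0.11) and Car9 (5.44 ± 0.20). Of 15 p53 targets 12 were detected, including Mdm2 (9.63 ± 0.17) and the cell cycle inhibitor gene Cdkn1a (7.71 ± 0.83). Heat shock genes passed in 10 of 12 cases, although the inducible chaperone Hspa1a did not (3.79 ± 0.14). Immediate early genes, which cell handling can induce, were above background in all arrays in 10 of 21 cases, and Fos, Jun and Egr1 only in some arrays. Interferon response genes passed in 13 of 25 cases, while Ifit1, an antiviral effector, was below background (4.11 ± 0.54). Of 18 homing and adhesion genes 10 were detected, including the CXCL12 receptor gene Cxcr4 (9.60 ± 0.31).

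Markers of other cell types that a sort could carry over were detected in part. For the counts here and in the next paragraph, 52.3% of all genes and 19.2% of genes typical of distant tissues passed in all arrays. A list with a share near the latter gives by itself no sign that such cells were carried over. In the neutrophil and granulocyte precursor list, 6 of 20 genes were above background in all arrays (Camp, Ngp, S100a8, S100a9, Chil3 and Lyz2) and 11 more in some. The erythroid list had 8 of 18 (Hbb-b2, Klf1, Epor, Car1, Car2, Rhd, Tfrc and Bpgm), of which the transferrin receptor gene Tfrc (11.26 ± 0.20) is also used by dividing cells in general. B cell genes passed in 6 of 22 cases (Cd22, Ighm, Igll1, Ly6d, Pou2af1 and Mzb1), with the B lineage genes Cd79a (4.99 ± 0.42) and Pax5 (4.91 ± 0.12) below background. Plasma cell genes passed in 5 of 10 (Sdc1, Jchain, Xbp1, Igha and Iglv1) and immunoglobulin segments in 5 of 20. Monocyte and macrophage genes passed in 6 of 25 (Csf1r, Lyz2, Ccr2, Fcgr1, Apoe and Tyrobp), while Adgre1 (4.93 ± 0.20) and Cd14 (4.28 ± 0.29) did not.

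Dendritic cell genes passed in 5 of 13 cases (Flt3, Bst2, Ly6d, Irf8 and Ccr9), several of which thymocytes also express, and natural killer cell genes in 1 of 12 (Gzma). Megakaryocyte genes were detected in 3 of 12 cases (Itga2b, Gp9 and Treml1), mast cell, basophil and eosinophil genes in 0 of 11, and stromal and endothelial genes in 5 of 19 (Pecam1, Sparc, Igfbp4, Pdgfrb and Alpl). Pdgfrb, a growth factor receptor gene of mesenchymal cells, was at 10.89 ± 0.48 while the collagen genes Col1a1 (4.34 ± 0.28) and Col3a1 (3.29 ± 0.18) were below background. MHC class II pathway genes were detected in 5 of 9 cases (Cd74, H2-Aa, H2-Ab1, H2-Eb1 and H2-Oa). Of 6 sex-linked genes 5 were detected, among them the X-inactivation transcript Xist and the Y-linked Kdm5d (8.34 ± 0.69). With the 99th percentile of the receptor families as threshold, the detected neutrophil genes numbered 2 and the detected erythroid genes 2. Without mouse 2, 13 neutrophil genes were detected.

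Between recipients, most genes differed little and a small set differed strongly. The median range of a detected gene was 0.27, or 1.21-fold, and 523 genes (5.50%) had a range over 1. Genes below background in any array, among them Hey1 and Il7r, were left out of this ranking. The widest range among genes detected in all arrays was that of Trgv4, a T cell receptor gamma variable segment. It was at 11.06 in mouse 1, 6.39 in mouse 2 and 11.63 in mouse 3 (37.9-fold). The gut homing receptor gene Ccr9 was at 6.31, 9.45 and 11.25 in mice 1, 2 and 3 (30.7-fold), and the metallothionein gene Mt2 at 9.39, 12.18 and 7.37. Ccnd2, which encodes the G1 cyclin D2, was at 10.09 and 9.08 in mice 1 and 2 and at 6.41 in mouse 3 (12.8-fold). All 6 of its probe sets above background in any array gave that order, some of them below background in mouse 3.

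The 25 genes with the largest range fell into several orders. Lower in mouse 3 than in both others were, besides Mt2 and Ccnd2, the genes Nbdy, Naip5, Scamp1, Tmem176b, Tceal9, Gadd45g, Nkd1 and Ahnak, the epithelial adhesion molecule gene Epcam (9.33, 8.79 and 6.26) and the glucose transporter gene Slc2a3 (10.07, 9.10 and 6.59). Highest in mouse 3 were Ccr9, Trgv4, P2ry10, Nmral1, the T cell receptor alpha segment Trav9d-3 (6.63, 9.48 and 9.92), the interferon-induced GTPase gene Gbp6 (7.08, 6.04 and 10.12) and the neutrophil and lysozyme genes S100a8, S100a9, Ngp, Camp and Lyz1. Chil3 was highest in mouse 1 and lowest in mouse 2 (9.39, 6.06 and 9.07). Tsc22d1 was highest in mouse 2 (7.04, 10.39 and 7.63).

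Each of the 523 genes was assigned to the mouse farther from the middle value, however small the difference between the gaps. By this rule mouse 3 stood apart in 301 genes (130 higher, 171 lower), mouse 2 in 140 (59 higher, 81 lower) and mouse 1 in 82 (46 higher, 36 lower). The other mice need not agree in these genes, as in Cym (12.23, 11.30 and 10.34), which was assigned to mouse 3. Across detected genes, Pearson correlations were 0.980 between mice 1 and 2, 0.969 between mice 1 and 3 and 0.964 between mice 2 and 3, where genes are not independent replicates. The numbers of genes differing by over 1 in these pairs were 144, 303 and 358. Among 190 of the 523 genes with a second detected probe set, that probe set had the same highest and lowest mouse in 151 (79.5%, 95% Wilson interval 73.2 to 84.6%), against a median of 19.5% for random pairs. The interval treats genes as independent. Agreement here concerns the order only, and the second probe set itself had a range over 1 in 125 of the 190. The count of 523 depended on which mice entered it, at 377 without mouse 1, 313 without mouse 2 and 164 without mouse 3, since 2 mice span a smaller range than 3. It was 263 with the 99th percentile as threshold.

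**Figure D2:**
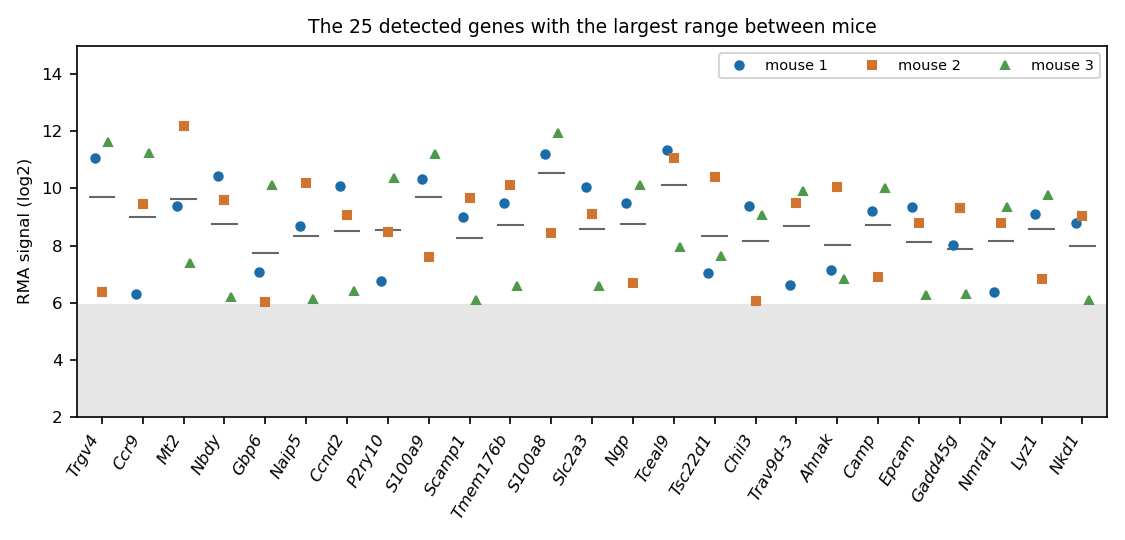
RMA signal (log2) of each mouse for the 25 detected genes with the largest range between mice, with the mean of 3 mice as a line and grey shading up to the highest background threshold of the arrays. Trgv4 spans 37.9-fold, Ccr9 30.7-fold and Ccnd2 12.8-fold.

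Cell cycle genes were higher in mouse 3. The G1 and S list was shifted there by 0.34 with 24 of 25 members higher, led by the ribonucleotide reductase subunit gene Rrm2 (11.96, 11.76 and 12.80 in mice 1, 2 and 3), E2f8 (9.98, 9.87 and 10.74) and Uhrf1 (11.99, 11.72 and 12.58). The G2 and M list was shifted by 0.33 with 24 of 25 members higher, led by the spindle checkpoint kinase gene Bub1 (10.46, 10.38 and 10.99) and the kinesin gene Kif11 (10.23, 10.38 and 10.84). The central 95% of random lists ran from -0.09 to 0.10 for both. The G1 and S list stood at -0.10 in mouse 1 and -0.30 in mouse 2, and the G2 and M list at -0.22 and -0.12. Without mouse 3 these values were 0.16, -0.16, -0.049 and 0.049, and without mouse 2 those in mouse 1 were -0.28 and -0.37. Without mouse 1 the G2 and M value in mouse 2 was -0.28. In mouse 3 the shift was -0.46 for glycolysis genes, with 3 of 14 members higher, and -0.26 for hypoxia response genes. Aldoa was at 11.97, 11.97 and 11.27 and the stress-induced mTOR inhibitor gene Ddit4 at 11.70, 11.26 and 10.63. Glycolysis stood at 0.18 in mouse 1 and 0.25 in mouse 2, and at -0.0031 and 0.0031 without mouse 3. Without mouse 2 the value in mouse 1 was 0.42, and without mouse 1 that in mouse 2 was 0.50. With the mean over members the glycolysis values in mice 1 and 2 were 0.34 and 0.16. The hypoxia shift in mouse 3 was -0.17 without mouse 2 and -0.16 without probe sets prone to cross-hybridisation, and the G2 and M value in mouse 2 was -0.00091 with the mean of all probe sets. Mouse 3 was also the array with the highest neutrophil and the lowest erythroid list values, the lowest 18S ribosomal RNA signal and the largest 3' to 5' difference of the beta-actin and transferrin receptor controls.

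T cell lists were higher in mouse 3 and lower in mouse 2, the directions that neutrophil genes also took in these arrays. Shifts in mouse 3 were 0.20 for T cell identity and 0.40 for the double-positive stage, against -0.16 and -0.22 in mouse 2. With the mean over members, T cell identity stood at 0.33 in mouse 3. Without mouse 2 the double-positive value in mouse 3 was 0.26, and without mouse 3 the values in mouse 2 were -0.084 and -0.091. The double-positive value in mouse 2 was -0.15 with the mean over members. Without mouse 1 the double-positive value in mouse 2 was -0.34. The identity genes with the largest deviation in mouse 3 were the surface gene Cd6 (6.78, 7.09 and 8.31) and the thymocyte regulator gene Tox (7.48, 8.90 and 9.14), and those of the double-positive stage were Ccr9 and the aquaporin gene Aqp11 (8.82, 9.37 and 10.54). In mouse 2 they were Cd247 (10.88, 10.06 and 11.06) and the coreceptor gene Cd8b1 (11.52, 10.87 and 11.87). The second detected probe set of Tox did not give the same highest and lowest mouse. Homing and adhesion genes were shifted by 0.29 in mouse 3 (0.089 without mouse 2) and -0.20 in mouse 2, where the integrin gene Itgb7 was at 6.78, against 8.69 and 8.75 in mice 1 and 3. The value in mouse 2 was -0.051 with the 99th percentile as threshold, and that in mouse 3 was 0.53 with the mean over members. The mature T cell list, with 5 detected members, stood at 0.51 in mouse 3 and -0.74 in mouse 2, values that became 0.059 without mouse 2 and 0.010 without mouse 3. With undetected members included they were 0.31 and -0.25. In mouse 1 it stood at -0.24, which changed sign without probe sets prone to cross-hybridisation (0.14). Its gene Ifngr1, the interferon gamma receptor, was at 10.36, 10.37 and 11.86. Notch targets stood at -0.16 in mouse 2, with Hes1 at 9.60, 8.23 and 9.01. Members went both ways there, and the targets Hey1 and Heyl, named after their values were seen, were highest in mouse 2 (7.72, 11.55 and 5.62 for Hey1 and 6.47, 7.01 and 4.88 for Heyl). They were left out of the shift because they did not pass background in mouse 3. With undetected targets included the shift was -0.14.

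The T cell receptor segments differed gene by gene. Trgv4 and Trgv1 (10.04, 7.45 and 9.82) were lowest in mouse 2 and Trav9d-3 was lowest in mouse 1, whereas the beta segment Trbv1 was at 12.54, 12.09 and 11.96. For Trgv4 and Trav9d-3, all 3 probe sets above background in any array gave the same order, although not all of them passed in every array. The list's shifts of 0.96, -1.32 and 1.47 rest on these 4 genes, and with undetected segments included they were 0.27, -0.0041 and -0.14. With the mean over members the value in mouse 1 was 0.22, and without probe sets prone to cross-hybridisation that in mouse 2 was -2.47. Without mouse 2 the shifts were -0.18 in mouse 1 and 0.18 in mouse 3, and without mouse 3 the shift in mouse 1 was 1.52.

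Interferon response genes were lower in mouse 2, with a shift of -0.39 and 1 of 13 members higher, and stood at 0.24 in mouse 1, a value that became -0.014 without mouse 2, 0.41 without mouse 3 and 0.15 with undetected members included. The tetherin gene Bst2 was at 9.85, 8.48 and 9.21 and the GTPase gene Gbp3 at 7.44, 6.03 and 7.29. The shift in mouse 3 was 0.15 (0.014 without mouse 2 and 0.36 without mouse 1), where the GTPase gene Igtp was at 9.90 against 8.79 and 8.45. In each mouse the interferon list took the direction of the neutrophil genes. Heat shock genes stood at 0.19 in mouse 1 (0.12 without mouse 3), where 9 of 10 were higher, among them the cochaperone gene Bag3 (9.05, 8.96 and 8.34). MHC class II genes stood at -0.91 in mouse 2 (-0.36 without mouse 3) and 0.84 in mouse 3, with H2-Aa at 6.46, 6.38 and 8.20, again the directions of the neutrophil genes. With undetected members included these were -0.18 and 0.56, without probe sets prone to cross-hybridisation -0.55 and 0.36, and with the mean over members the value in mouse 2 was -0.55. The value in mouse 1 (-0.38) changed sign with the choice of probe sets and without mouse 3.

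Among lists of other cell types, neutrophil and granulocyte precursor genes had the largest shifts, at 0.95 in mouse 1, -3.14 in mouse 2 and 2.00 in mouse 3. Without mouse 2, mice 1 and 3 differed much less, with shifts of -0.62 in mouse 1 and 0.62 in mouse 3, without mouse 3 the value in mouse 1 was 2.73, and without mouse 1 that in mouse 3 was 3.29. With undetected members included, the values in mice 1 and 2 were 0.33 and -1.52. S100a8, a calprotectin subunit, was at 11.19, 8.43 and 11.95, S100a9 at 10.32, 7.61 and 11.21, and the granule protein gene Ngp at 9.50, 6.68 and 10.12. Monocyte genes were shifted by -0.35 in mouse 2 (-0.54 without mouse 1) and 0.40 in mouse 3, led by Lyz2 (8.72, 6.73 and 9.31), which the neutrophil list also holds. Over all settings with 3 mice these values ran from -0.63 to -0.25 and from 0.26 to 0.88. The erythroid list went another way, at 0.25 in mouse 2 (0.41 without mouse 1 and 0.16 with the mean of all probe sets) and -0.42 in mouse 3 (-0.25 without mouse 2). In mouse 3, 3 of its 8 detected members were higher, and 1 of the 8 had a range over 1, the carbonic anhydrase gene Car2 (8.48, 8.90 and 6.88). Outside the rule for named genes and chosen after their values were seen, the band 3 gene Slc4a1 was at 8.53, 9.51 and 4.74 and the haem synthesis gene Alas2 at 7.13, 7.52 and 5.51.

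**Figure D3:**
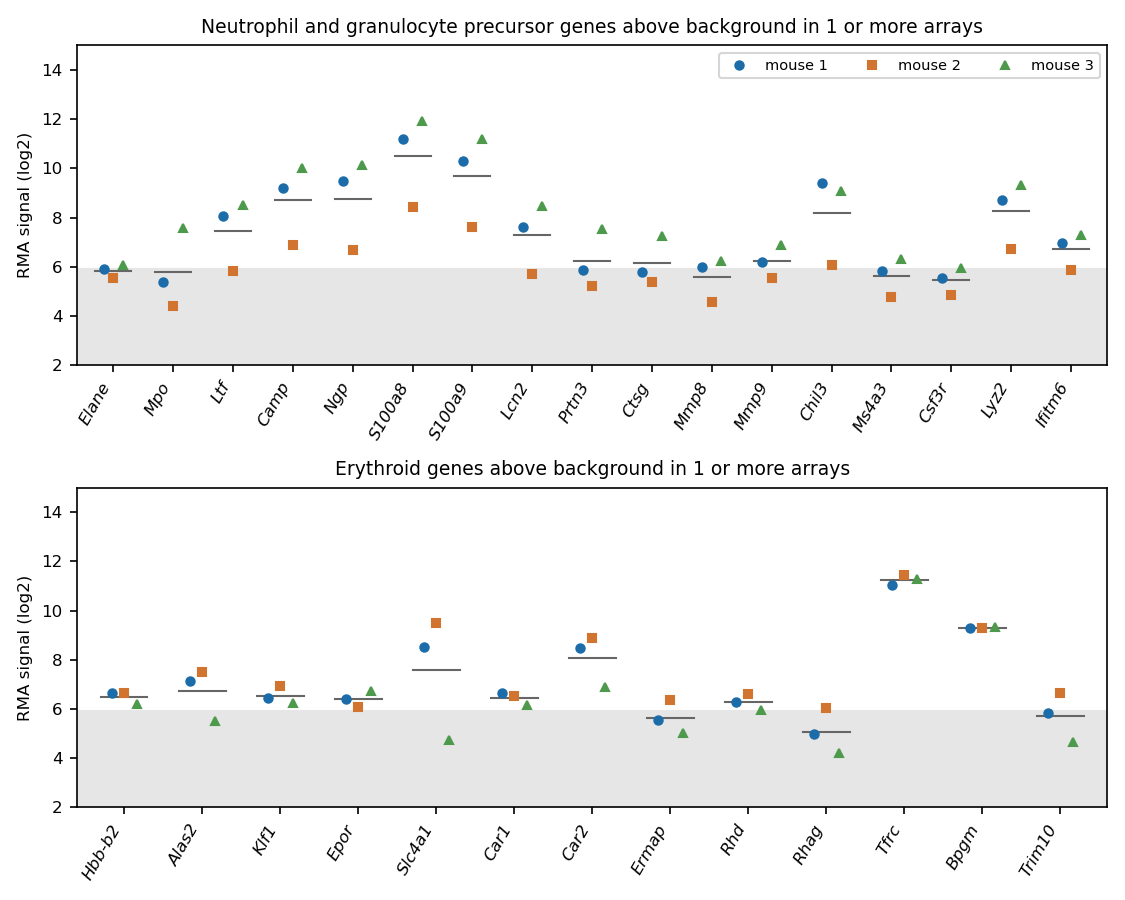
RMA signal (log2) of each mouse for neutrophil and granulocyte precursor genes and for erythroid genes that passed background in 1 or more arrays, with the mean of 3 mice as a line and grey shading up to the highest background threshold. S100a8 drops to 8.43 in mouse 2, whereas Slc4a1 drops to 4.74 in mouse 3.

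B cell genes were lower in mouse 1 (-0.47), where Ly6d, a surface gene shared with early lymphoid cells, was at 9.96 against 12.59 and 12.87, and stood at 0.22 in mouse 2 and 0.25 in mouse 3. The value in mouse 2 was -0.13 without mouse 1, 0.46 without mouse 3 and -0.20 with undetected members included, and that in mouse 3 was 0.13 without mouse 1 and 0.40 without mouse 2. Over all settings with 3 mice the value in mouse 1 ran from -0.73 to -0.20, that in mouse 2 from -0.20 to 0.38 and that in mouse 3 from 0.19 to 0.47. Ly6d and Ccr9 also led the dendritic cell list, at -0.42 in mouse 1 (-0.063 without mouse 3 and -0.81 without mouse 2) and 0.80 in mouse 3. Over those settings the former ran from -1.26 with the mean over members to -0.065, and the latter from 0.046 with undetected members included to 1.17. Plasma cell genes stood at -0.40 in mouse 2 and 0.68 in mouse 3, and immunoglobulin segments at -0.40 and 0.68, with the shared members Igha (6.88, 7.27 and 8.45) and Iglv1 (7.50, 6.06 and 7.46). With undetected members included, the plasma cell value in mouse 3 was 0.15 and the immunoglobulin values were -0.082 and 0.13. Without probe sets prone to cross-hybridisation the immunoglobulin values were -0.13 and 0.40, and over all settings with 3 mice they reached -0.59 and 1.12. The plasma cell value in mouse 2 was -0.69 with the mean over members. Without mouse 2 the values in mouse 3 were 0.031 and 0.20. Without mouse 1 the values in mouse 2 were both -1.18, and without mouse 3 that of the immunoglobulin segments was -0.13. Sex-linked genes stood at -0.50 in mouse 2, where Kdm5d was at 7.55 against 8.68 and 8.78, and at 0.44 in mouse 3, where Xist was at 7.67 against 6.66 in both others. The list pools Xist with Y-linked genes, so its shift does not point to either sex. With the 99th percentile as threshold the values in mice 2 and 3 were 0.040 and 0.12, without mouse 3 that in mouse 2 was -0.013, and without mouse 2 the value in mouse 3 was 0.10. Without mouse 1 they were -1.01 in mouse 2 and 1.01 in mouse 3.

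Of 96 list values, 48 lay outside the central 95% of random lists. By chance 4.8 would, if genes of a list varied as independently as randomly drawn genes, which cannot be assumed. Members of a list are regulated together, several lists share genes, and the shifts of the mice are tied to each other because each is measured against the others. Lists within the central 95% in all mice were early progenitor genes, T-ALL genes, Myc targets, the PI3K and mTOR pathway, the BCL2 family, immediate early genes, p53 targets, megakaryocyte genes, stromal genes, widely expressed genes and ribosomal proteins. For early progenitor genes this covers only the 8 detected in all arrays. Kit and Il7r, above background in mouse 3 alone, did not enter that shift. With the 99th percentile as threshold 22 of the 32 lists kept enough members, and 24 of 66 values lay outside. With a mouse left out each list gives a pair of values of opposite sign and equal size, so that the 44, 26 and 24 of 64 values outside without mouse 1, 2 and 3 stand for 22, 13 and 12 of 32 lists, against 21 lists as reported. Of the 48, 35 moved by over 1.5 times when a mouse was left out and 34 under some other setting. The 5 that did neither were the G1 and S, G2 and M and glycolysis lists in mouse 3 and the Notch target and interferon response lists in mouse 2.

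**Figure D4:**
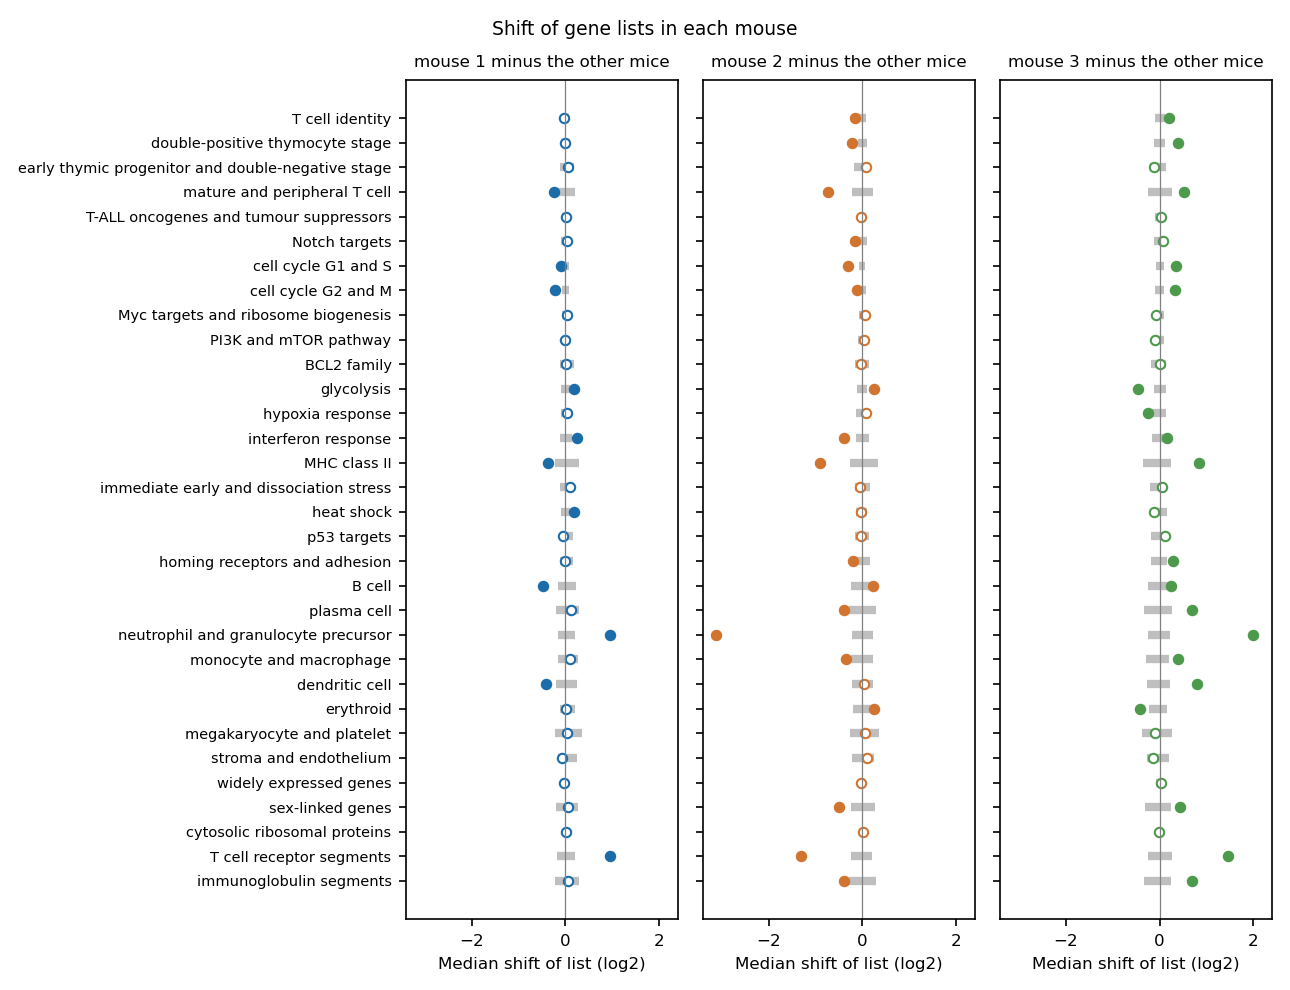
Median shift (log2) of 32 gene lists in each mouse against the mean of the other mice, as points, with grey bars for the central 95% of random lists of the same size and mean signal; filled points lie outside the bars. Neutrophil genes reach -3.14 in mouse 2 and 2.00 in mouse 3 (0.62 against mouse 1 alone), and the cell cycle lists reach 0.34 and 0.33 in mouse 3.

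Control measures were closest between arrays for Gapdh and the spike-in controls and further apart for the transferrin receptor and 18S ribosomal RNA. The signal at the 3' end of the beta-actin transcript exceeded that at the 5' end by 0.53, 0.57 and 0.61 in mice 1, 2 and 3 (mean 0.57 ± 0.04), and the Gapdh difference was -0.03, 0.03 and 0.01. The transferrin receptor control, a longer transcript, gave 1.99, 1.80 and 2.24. Residual 18S ribosomal RNA signal was 11.43, 11.81 and 10.97, lowest in mouse 3, while hybridisation controls were at 10.76, 10.77 and 11.03 and polyadenylated spike-in controls at 7.62, 7.55 and 7.58.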

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

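A pair of settings was chosen after the results had been seen, namely both exclusions of genes linked to other cell types, and all other settings were planned. Centring the arrays, repeating the quantile normalization and using the other deposited table changed little or nothing, since the values were already quantile-normalized and both tables agree, so these settings say nothing about stability. The count of genes with a range over 1 (523 as reported) was 520 and 529 under the first pair, 370 with the mean of all probe sets, and 503 without probe sets prone to cross-hybridisation. It was 263 with the 99th percentile of the receptor families, 494 with a fixed signal of 6, 883 for genes detected in at least 1 array, 993 without a detection filter and 91 for a range over 2. Without members of other cell type lists it was 504, and without genes ordered over the mice like neutrophil or erythroid genes it was 270. Changes under other thresholds, detection filters, exclusions and the larger range follow from what those settings admit, and the cause of the others was not tested.

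With the 99th percentile, 2 neutrophil and 2 erythroid genes were detected, too few for a shift of either list, 24 of 66 list values lay outside the central 95%, and the sex-linked shift in mouse 2 turned to 0.040. With the mean over members, T cell identity stood at -0.23 in mouse 1 and 0.33 in mouse 3, the double-positive stage at -0.37 in mouse 1, where Ccr9 was low, and mature T cell genes at 0.091 in mouse 1. Without probe sets prone to cross-hybridisation, mature T cell genes stood at 0.14 and MHC class II genes at 0.20 in mouse 1. The latter were at 0.11 with the mean of all probe sets. With all measured members, MHC class II was at 0.0030 in mouse 1, B cell genes at -0.20 in mouse 2 and T cell receptor segments at -0.14 in mouse 3. The cause of these sign changes was not tested.

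Leaving out each mouse in turn gave 164 to 377 genes with a range over 1, 24 to 44 of 64 list values outside, 6 to 13 neutrophil genes detected, and 94.6 to 98.2% of second probe sets in the same order, a share that rises because 2 mice have fewer possible orders. Shifts in mouse 1 spanned -0.17 to 0.084 for T cell identity, -0.26 to 0.091 for the double-positive stage, -0.28 to 0.16 for G1 and S, -0.0031 to 0.42 for glycolysis, -0.014 to 0.41 for interferon response, -0.64 to 0.36 for MHC class II, -0.62 to 2.73 for neutrophil genes, -0.37 to 0.25 for erythroid genes and -0.18 to 1.52 for T cell receptor segments. Shifts in mouse 2 spanned -0.61 to 0.010 for mature T cell genes, -0.28 to 0.049 for G2 and M and -0.13 to 0.46 for B cell genes. Each such value compares single mice. The G1 and S shift in mouse 3 stayed between 0.28 and 0.43, the neutrophil shift in mouse 2 between -3.29 and -2.73 and that in mouse 3 between 0.62 and 3.29, and the erythroid shift in mouse 3 between -0.41 and -0.25. A list value could count as reversed only if it lay outside the central 95% as reported. With a mouse left out, 288 values moved by less than the spread between mice or by at most 1.5 times of a count, 93 moved further and 9 reversed. Under the other settings, 1164 stayed within those bounds, 114 moved further and 8 reversed. These counts include the centred arrays, the repeated quantile normalization and the other deposited table. Those settings leave values unchanged or nearly so, and the 1164 therefore overstates how stable the values are.

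No paired analysis was possible because the series has 1 group. The comparison of fold changes from the authors was not run, since no such columns were analysed here. Genes within about 1 log2 unit of the background are those whose detection depends most on the threshold.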

Other observations

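The agreement of second probe sets and the random lists set against the gene lists were planned, all other tests in this part were chosen after the result they concern had been seen, and so were the single genes named in the next sentences, which stand for no tested group. Among genes for guanylate-binding proteins, which are interferon-induced GTPases, Gbp8 (9.44, 8.50 and 11.37 in mice 1, 2 and 3), Gbp6 (7.08, 6.04 and 10.12) and Gbp7 (8.25, 6.54 and 8.38) were highest in mouse 3, whereas Gbp3, a member of the interferon response list, was highest in mouse 1 (7.44, 6.03 and 7.29). The inflammasome sensor genes Naip5 (8.68, 10.19 and 6.14) and Naip6 (8.55, 9.49 and 6.70) were highest in mouse 2 and lowest in mouse 3. These neighbours are similar in sequence, so their probe sets need not be independent.

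The tight junction genes Cldn4 (9.67, 8.31 and 6.87) and Tjp3 (9.23, 8.64 and 7.06) were lowest in mouse 3, each as single genes. So was Epcam (9.33, 8.79 and 6.26), whose second probe set gave the same order with a range of only 0.57. The D cyclin gene Ccnd2 was at 10.09, 9.08 and 6.41, and 6 of 6 probe sets above background in any array gave that order. The guanine nucleotide exchange factor gene Rasgrp1 was at 5.02, 4.58 and 8.75, and the Notch target gene Hey1 at 7.72, 11.55 and 5.62, detected by 1 probe set.

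Neutrophil genes were lower in mouse 2 and highest in mouse 3, in cells sorted for EGFP. The shift of -3.14 in mouse 2 was not shared by genes of similar signal. Of random lists matched on mean signal, 2.5% lay below -0.23 and their median was 0.0081. Scaling between arrays would move such genes alike, but quantile normalization holds them level in any case. The comparison could therefore not have shown scaling and decides nothing about it. Carry-over of all blood cells in 1 proportion is argued against by the erythroid shift of -0.42 in mouse 3, the array with the highest neutrophil signal. Whether a single cell source of fixed make-up gave the signal in each array cannot be told apart from other sources, because the comparison of primary granule genes with later neutrophil genes (ratio of the median excesses 3.93) rests on Mpo, Prtn3 and Ctsg, of which 1 of 3 was above background in mouse 1 and 0 of 3 in mouse 2, while Elane, left out as close to background, gave 1.48. Neutrophil-lineage cells, which an EGFP gate should exclude, and expression by the leukaemia itself both may contribute, and a difference between organs was not tested because the labels give no organ per array.

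The erythroid list was lower in mouse 3, with 3 of 8 detected members higher. Its beta-globin gene Hbb-b2 had a range of at most 1, as had every member detected in all arrays but Car2. Why Hbb-b2 differed less than the globin probe sets described next was not tested. Adult globin probe sets that did not enter the list's shift, each matching several gene copies, had a median shift of -3.71 in mouse 3. The list also names the beta-globin genes Hbb-b1, Hbb-bt and Hbb-bs, which no probe set named alone. The beta-globin probe set used here may measure them and is then not separate from the list. For 3 of the globin probe sets the shift was 12.4-fold to 13.2-fold, as in 1 at 13.38, 13.53 and 9.73. The other, below background in mouse 3, was at least 15.6-fold lower. This is what red cell precursors or their RNA in arrays 1 and 2 would give. The globin shift was not shared by probe sets of similar signal. Of random groups of 4 probe sets drawn from the 1000 nearest to each in mean signal, 2.5% lay below -0.23 and the lowest was -0.96. Quantile normalization holds such groups level in any case, so this comparison could not decide on scaling between arrays. Sorting by EGFP should remove such cells, RNA released from them could still be carried along, and whether mouse 3 came from another organ than the others stays open.

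Genes differing over 2-fold between recipients could in principle reflect noise of single probe sets. Only 190 of the 523 genes had a second detected probe set. Of these probe sets, 79.5% gave the same highest and lowest mouse, against 19.5% for random pairs. That argues against noise for the order of these 190 genes as a set, but 125 of the second probe sets had a range over 1. Carry-over of neutrophil or erythroid cells cannot be told apart from other sources by the order over the mice. Of the 91 genes with a range over 2, 49.5% followed neither the neutrophil nor the erythroid order, below the 66.7% for equally frequent orders, and so did Chil3, 1 of 7 members of those lists with a range over 1. Other cell types and divergence of the leukaemic cells in each recipient, as for Ccnd2 and Il7r, both remain open as hypotheses. Neither was tested, since the design has 1 group.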
